A study of Drosophila melanogaster with 4 samples.

How the data were processed

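The data were direct RNA sequencing libraries of *Drosophila melanogaster* made on an Oxford Nanopore device. RNA was extracted with TRIzol, enriched for poly(A) RNA on oligo(dT) beads and prepared with the RNA002 direct RNA kit with its reverse-transcription step, per the labels' protocols. In this method an adapter is joined to the poly(A) tail, so each read starts at the 3' end of an RNA. There were 4 libraries, 1 in each group: ovaries with a control hairpin against arrestin2, ovaries with a hairpin against vreteno, ovarian somatic cells (OSCs) with siGFP and OSCs with siPIWI. Samples were grouped by the genotype or treatment in the labels.

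The authors deposited, for each library, whole-number counts at every position of 150 reference sequences, 672432 positions in all. The column names, per the file headers, give the sequence, the position and the value, and no strand. Minimap2 is named in the submitters' processing notes. Its version and settings, the reference set, the treatment of reads that match several sequences and any filter were not given in the sources used here. Between 906 and 5800 positions per library held a count above 0. Of the transposon counts, 67.9% to 89.9% lay in the last 10% of the consensus sequences. Read coverage would fill whole stretches of sequence, so the deposited counts were read as the number of reads whose 3' end fell on a position. This reading comes from the values. The unit was therefore taken as reads without normalization. Whether a read that matches several sequences was counted more than 1 time is unknown, and the counting intervals assume that it was not.

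The design fixed before the data were examined had assumed base coverage. Reads per element, the sum of the counts over its positions, took the place of mean coverage. A drop of coverage inside an element and the antisense share could not be computed from read ends without strand and were left out. Of the 150 sequences, 124 were transposons. The other 26 (satellites, telomere-associated repeats, the rDNA spacer, Stellate, Suppressor of Stellate and a few chromosomal regions) were kept out of the transposon totals. Positions are given on the consensus sequence, counted from 1. No genome coordinate was used, and the gene annotation supplied with the data was not used here. Levels of *vreteno* and *piwi* mRNA were not analysed here, so the knockdowns themselves were not checked.

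The files hold only reads assigned to these sequences, so the full depth of each library is unknown. Within each comparison the knockdown library was scaled to its control by the median ratio of reads over transposons with at least 10 reads in both libraries. This ratio was 0.903 in ovary (30 transposons, 95% interval of the median 0.761 to 1.07) and 1.99 in OSCs (54 transposons, 1.55 to 2.63). Any scaled fold therefore carries a common factor of 0.845 to 1.19 in ovary and 0.754 to 1.28 in OSCs, beyond its own counting interval. This range covers the median alone, and takes the typical transposon as unchanged by the knockdown, which was not checked. Total transposon reads gave a ratio of 2.17 in ovary and 2.88 in OSCs, and non-transposon reads 0.603 and 2.14. Both ovary ratios and the OSC ratio of total reads lie outside the intervals of the median. Log2 ratios were computed on scaled reads with a pseudocount of 1 read, which understates the change of elements with few reads. Transposons with at least 10 reads in the library with more reads entered the counts. That minimum was set after the totals had been seen, since the planned one was written for coverage. An element was called higher or lower at a log2 ratio of at least 2 in size (4-fold).

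With 1 library per group no test across conditions was possible and no p-values are given. Folds are ratios of scaled reads, with exact conditional 95% intervals. Shares of reads have exact Clopper-Pearson 95% intervals. A control count of 0 was replaced by a floor of 3 reads per library to give a lower bound. These intervals and bounds cover counting error only, and compare 2 libraries rather than 2 conditions.

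Before the data were examined, 8 lists of transposons were fixed from general knowledge: the gypsy group with an envelope (env) gene, the mdg1 group, other Ty3/gypsy elements, Bel-Pao, copia-like, telomeric, other non-LTR elements and DNA transposons. Transposon names that consist of digits are written in quotation marks, to set them apart from measured values. Of 133 listed names, 111 were matched to the files, ignoring case, hyphens, "-element" and the prefix or suffix "Repbase" and "new". The Repbase and new forms were added to the matching rule once the names in the files were seen. A list's median log2 ratio was set against 10000 random lists of the same size drawn from the same 3 classes of read number, where at least 3 members entered. Its 95% interval came from 1000 Poisson resamples of the reads. The named transposons were, per comparison, the 15 with the largest log2 ratio in size among those whose highest single position changed in the same direction, the 5 with most reads in each library and 12 fixed names. Others, named for being at or past a stated threshold or for the position of their ends, were chosen after their values were seen.

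The share of read ends in the last 30% of each consensus was compared between the libraries of a pair for transposons with at least 10 reads in both. This comparison was added after the data were seen. Alternatives changed the pseudocount (10 reads), the minimum (none, or 50 reads), the scaling (total transposon reads, or none), the summary (highest single position, or ends in the last 30% only) and the size threshold (2-fold). Scaling to the non-transposon sequences was added later. The procedure was tested on simulated data, 50 Poisson data sets per comparison over 124 transposons. Of the 8-fold changes in elements past the read minimum, 89.9% were called for ovary depth (266 of 296) and 90.5% for OSC depth (294 of 325). Simulated elements below the minimum are left out of these rates and the next ones. Changes of 2-fold were called in 3.10% and 3.66%, and unchanged elements in 0.0718% and 0.269%. The median estimated depth ratio was 0.966 for a true 0.903 in ovary and 2.08 for a true 1.99 in OSCs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.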

Results

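Poly(A) RNA was sequenced directly from 2 pairs of samples in which the piRNA pathway was reduced in somatic cells of the ovary. piRNAs are small RNAs that guide Argonaute proteins of the Piwi class to transposon RNA and silence it. In the first pair, the tj-GAL4 driver, active in the somatic cells of the ovary, expressed a hairpin against *vreteno*, which encodes a Tudor-domain protein needed to make piRNAs, or a control hairpin against *arrestin2*. In the second pair, OSCs, a cultured line of somatic follicle cells, received siRNA against *piwi* or against GFP. The series concerns transfer of retrotransposons from cell to cell, and these libraries address which transposon RNAs are present, and where they end, once somatic silencing is reduced.

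The transposon reads numbered 2382 in the control ovaries, 5156 in the vreteno knockdown ovaries, 57045 in siGFP OSCs and 164243 in siPIWI OSCs. Each group had 1 library. The ovary values are therefore the less precise ones. A transposon with no read could still hold up to 0.126% of transposon reads in the control ovaries and up to 0.00526% in siGFP OSCs. Of 124 transposons, 111 had a read in at least 1 library.

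The retrotransposon copia dominated the OSC libraries. It took 73.2% of transposon reads in siGFP OSCs (95% interval 72.9 to 73.6) and 52.9% in siPIWI OSCs (52.7 to 53.2), against 20.9% (19.3 to 22.6) in control ovaries and 17.5% (16.5 to 18.6) in vreteno knockdown ovaries. The endogenous retrovirus springer came second in both OSC libraries, with 16.2% (15.9 to 16.5) and 18.9% (18.7 to 19.1). In control ovaries the most abundant elements after copia (498 reads) were the LTR element '412' (256 reads), the short DNA repeat DNAREP1 (240 reads), the DNA transposon pogo (218 reads) and the non-LTR element Doc (176 reads).

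The first comparison asked which transposon RNAs accumulated in ovaries when *vreteno* was knocked down in the soma. Of the transposons past the read minimum, 4 of 9 endogenous retroviruses of the gypsy group and 5 of 6 elements of the mdg1 group were at least 4-fold higher, and HMS-Beagle2 and Transib1 were the only others. ZAM had 3 reads in the control and 573 in the knockdown, a scaled fold of 211.5 (95% counting interval 72.0 to 1028). Gypsy went from 5 to 367 reads (81.3-fold, 34.5 to 252) and springer from 15 to 383 reads (28.3-fold, 16.9 to 51.0). All 3 carry an env gene of the kind that retroviruses use to fuse with cells. Of 45 transposons past the read minimum, 11 were at least 4-fold higher and 0 at least 4-fold lower. The counting interval lay above 1 for each of the 11, which the read minimum and the 4-fold rule largely ensure.

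In the gypsy group with env, 9 of the 14 members in the files passed the minimum. Of these, 4 were at least 4-fold higher: ZAM, gypsy, springer and Quasimodo (6.64-fold, 2.28 to 26.3). The list's median log2 ratio was 1.99 (interval 1.24 to 3.11), at the 95.5th percentile of random lists. Rover was 3.64-fold higher (lower bound 1.51, 7 against 23 reads) and gypsy6 5.54-fold (1.18 to 52.0, 2 against 10 reads), both under the 4-fold rule on the log2 scale with the pseudocount. The element '297' had a fold of 1.96 (0.952 to 4.21), '17.6' a fold of 0.954 (0.536 to 1.69), opus a fold of 1.22 (0.470 to 3.20) and gtwin, below the minimum, a fold of 2.95 (0.709 to 17.3), so no difference was detectable for these 4 at this depth.

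In the mdg1 group all 6 members passed the minimum and 5 were at least 4-fold higher, with a median log2 ratio of 3.0 (2.47 to 3.73), at the 98.3rd percentile of random lists. Stalker2 was 28.8-fold higher (9.49 to 143), mdg1 14.5-fold (7.64 to 31.0), Tabor 13.3-fold (3.30 to 116), Stalker 7.20-fold (2.50 to 28.4) and blood 7.16-fold (5.29 to 9.89). The sixth, '412', was 3.94-fold higher (3.42 to 4.54), just under the rule, and had the most reads in the knockdown library, 910. This fold joins 2 sets of reads, split after the data were seen. Those ending in the last 30% of the consensus went from 15 to 406, a fold of 29.97 (17.95 to 54.04). Those ending further upstream went from 241 to 504, a fold of 2.32 (1.98 to 2.71). Beyond these 2 groups, the Ty3/gypsy element HMS-Beagle2 was 17.7-fold higher (5.71 to 88.9) and the DNA transposon Transib1 12.2-fold (1.77 to 524, 1 against 11 reads).

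The remaining lists had medians whose intervals included 0. The 7 non-LTR elements had a median log2 ratio of 0.06 (-0.38 to 0.32), with Doc at a fold of 1.07 (0.861 to 1.33) and G5, from 3 to 12 reads, at 4.43 (1.20 to 24.5). The I-element had 2 and 9 reads, below the minimum, a fold of 4.98 (1.03 to 47.4); its highest single position held 1 read in each library. The 7 DNA transposons had a median of -0.18 (-0.46 to 0.33). Among them pogo was lower, at a fold of 0.706 (0.567 to 0.877), though not when the libraries were scaled to non-transposon sequences (log2 ratio 0.08), and INE-1 had 3 and 12 reads (4.43-fold, 1.20 to 24.5). The entry DNAREP1, with far more reads (240 and 202), was at 0.932 (0.769 to 1.13). Whether INE-1 and DNAREP1 are separate elements was not checked, so the INE-1 value holds for that entry alone. The other Ty3/gypsy elements had a median of 0.50 (-0.03 to 0.93), the copia-like elements 0.35 (-0.33 to 1.0), Bel-Pao -0.19 (-0.77 to 0.27) and the telomeric elements -0.50 (-1.37 to 0.08). The telomeric retrotransposon HeT-A was at a fold of 0.554 (0.242 to 1.19) and the Bel-Pao element roo at 0.664 (0.418 to 1.04). Copia itself was 2.01-fold higher (1.80 to 2.24), a direction that turned when libraries were scaled to total transposon reads (log2 ratio -0.26). That scaling lowers log2 ratios by 1.26, or by less for elements with few reads because of the pseudocount. With it, 7 of the 11 elements stayed at least 4-fold higher and 2 elements were at least 4-fold lower. With a pseudocount of 10 reads 7 of the 11 stayed.

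**Figure D1:**
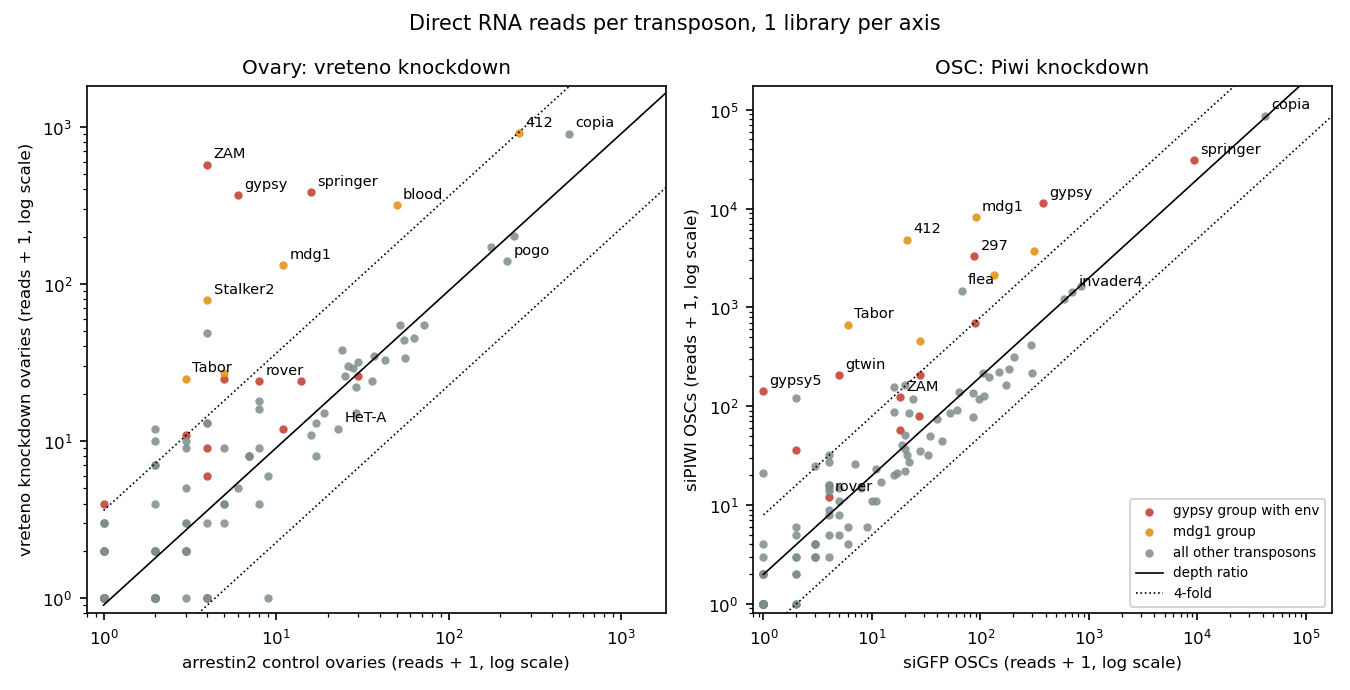
Reads per transposon (plus 1, log scales) in the control library (x axis) and the knockdown library (y axis), for ovaries on the left and OSCs on the right. Each point is 1 transposon coloured by list, the solid line is the depth ratio and the dotted lines lie 4-fold above and below it. ZAM (3 and 573 reads) and gypsy (5 and 367 reads) lie farthest above the line in ovary, and '412' (20 and 4835 reads) in OSCs among elements with over 10 control reads.

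The second comparison asked the same of cultured follicle cells after knockdown of *piwi*, which encodes the nuclear Argonaute that silences transposons through piRNAs. The mdg1 group had the highest median of the 8 lists, followed by the gypsy group with env. The element '412' went from 20 to 4835 reads (122-fold, 78.8 to 200), Tabor from 5 to 668 (67.3-fold, 28.7 to 208) and mdg1 from 89 to 8137 (46.1-fold, 37.4 to 57.4). Of 73 transposons past the minimum, 18 were at least 4-fold higher with the pseudocount and 0 at least 4-fold lower. With elements at 0 control reads called on the floor of 3 reads, 17 were, without Transib1. At a 2-fold threshold the numbers were 28 and 4. The 18 all had counting intervals above 1, which the same rules largely ensure.

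All 6 members of the mdg1 group were at least 4-fold higher, with a median log2 ratio of 4.28 (4.03 to 4.63), at the 99.7th percentile of random lists. Stalker was 8.43-fold higher (5.72 to 12.9), Stalker2 8.26-fold (6.92 to 9.93) and blood 6.15-fold (5.47 to 6.93). The group's share of transposon reads was 1.02% in siGFP and 12.2% in siPIWI OSCs.

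In the gypsy group with env, 12 of 14 members passed the minimum and 5 were at least 4-fold higher, with a median log2 ratio of 1.95 (1.74 to 2.61), at the 98.1st percentile. Gypsy5 had 0 reads in the control and 141 in the knockdown, at least 23.7-fold higher on the floor of 3 reads, with an exact lower bound of 19. The element gtwin was 25.7-fold higher (9.88 to 95.2), '297' 19.1-fold (15.5 to 24) and gypsy 15.2-fold (13.7 to 16.9). Idefix had 1 read in the control and 35 in the knockdown, a log2 ratio of 3.42 with a fold interval of 2.96 to 716. Quasimodo at 3.99-fold (3.19 to 5.04), '17.6' at 3.84-fold (2.57 to 5.97) and ZAM at 3.62-fold (2.17 to 6.41) were just under the rule. Springer, already at 9220 reads in the control, was 1.70-fold higher (1.66 to 1.74). Rover had 3 and 11 reads, a fold of 1.85 (0.488 to 10.3).

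Outside these 2 groups, flea was 11.2-fold higher (8.78 to 14.6) and HMS-Beagle2 5.27-fold (3.10 to 9.65), both Ty3/gypsy elements. Pifo, an element described from another fly species, had 1 and 120 reads (60.5-fold, 10.6 to 2407). Transib1 had 0 and 20 reads, at least 3.36-fold higher on the floor of 3 reads, with an exact lower bound of 2.49. Among the 12 non-LTR elements past the minimum, 5 were at least 2-fold higher, including F-element (4.32-fold, 2.68 to 7.36), Doc (2.89-fold, 1.66 to 5.38) and the I-element (2.56-fold, 1.63 to 4.20). That list's median was 0.84 (0.17 to 1.22), at the 73.3rd percentile of random lists, and it was -0.09 when the highest single position was used in place of all reads.

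Other abundant elements lay near the depth ratio. Copia was at a fold of 1.05 (1.04 to 1.06), which is within the interval of the median scaling. It turned below 1 with total scaling (log2 ratio -0.47) and with scaling to non-transposon sequences (-0.04). The Ty3/gypsy elements mdg3, invader4 and gypsy12 were at 0.974 (0.896 to 1.06), 1.03 (0.937 to 1.13) and 1.03 (0.932 to 1.14). The other Ty3/gypsy list had a median of 0.04 (-0.15 to 0.17) and the copia-like list 0.07 (-0.02 to 0.21). The telomeric list was at -0.06 (-0.57 to 0.38), with HeT-A at a fold of 0.748 (0.471 to 1.20), and the DNA transposons were at -0.29 (-0.45 to 0.08). The Bel-Pao list was at -0.48 (-0.75 to -0.28), with roo at a fold of 0.810 (0.612 to 1.08), and at 0.51 when the reads were not scaled for depth. Its member diver was lower, at a fold of 0.363 (0.303 to 0.434). Outside that list, so were S2 at 0.456 (0.331 to 0.629), Circe at 0.480 (0.385 to 0.598) and G5A at 0.488 (0.288 to 0.826). These 4 were at least 2-fold lower, and 11 of 73 transposons had intervals below 1. Raw reads were 85 and 77 for S2, 172 and 164 for Circe and 32 and 31 for G5A, so these folds rest on the scaling.

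Across the 40 transposons past the minimum in both comparisons, the 2 sets of log2 ratios had Pearson's r of 0.575 (0.402 to 0.768 by resampling elements) and Spearman's rho of 0.723. This correlation is across transposons, which are not independent replicates, and the comparisons share no library. Of the 40, 11 were at least 4-fold higher in ovary and 13 in OSCs, and 8 in both, against 3.58 for independent lists. On the floor bound, which leaves out Transib1 in OSCs, 12 passed in OSCs and 7 in both, against 3.30. The 8 were gypsy, mdg1, Tabor, Stalker, Stalker2, blood, HMS-Beagle2 and Transib1. Elements with few control reads pass the minimum only through the knockdown library, which the count for independent lists and the correlation ignore. Tabor (2 and 24 reads in ovary, 5 and 668 in OSCs) and Transib1 (1 and 11, 0 and 20) entered both comparisons in this way. In ovary gypsy, Stalker, Stalker2 and HMS-Beagle2 did so too. ZAM, springer and Quasimodo passed the rule in ovary alone, and '412', '297', flea, Dm88 and F-element in OSCs alone. In ovary '412' was just under the rule, at a log2 ratio of 1.97. Passing in 1 comparison does not show a difference: the log2 difference of the folds (OSC minus ovary, interval widened for 39 elements) included 0 for Quasimodo (-0.74, -3.30 to 1.83), Dm88 (2.24, -1.41 to 5.88) and F-element (0.68, -1.69 to 3.06).

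**Figure D2:**
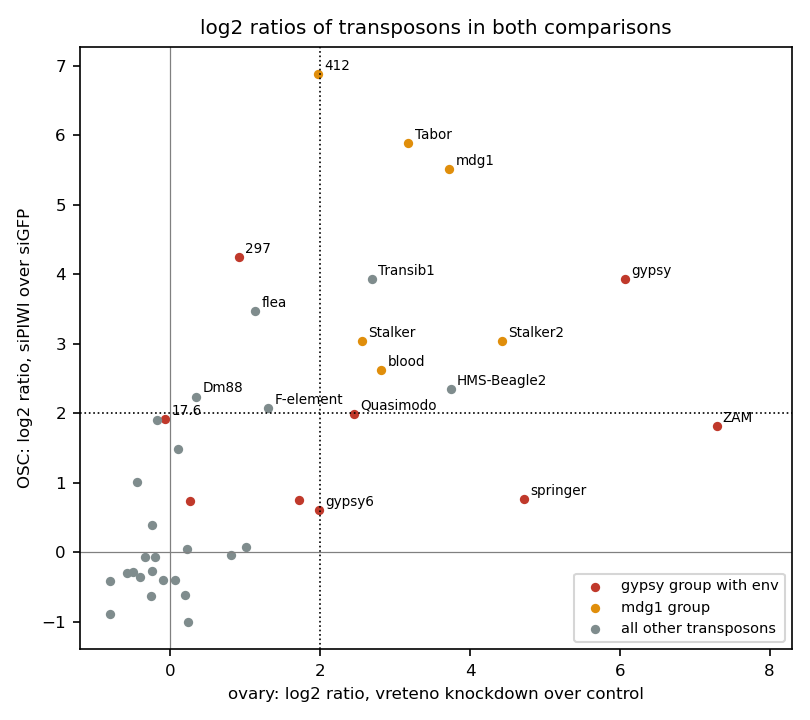
Log2 ratio of knockdown over control in ovary (x axis) and OSCs (y axis) for the 40 transposons past the read minimum in both comparisons, each point 1 transposon coloured by list, with dotted lines at a log2 ratio of 2. ZAM has a log2 ratio of 7.29 in ovary and 1.81 in OSCs, and '412' has 1.97 and 6.88.

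The position where reads ended was compared next, since the 3' end of a read marks where its RNA was polyadenylated or captured. Most counts lay near the 3' end of the element, which was part of the ground for reading them as read ends and so is no separate result. Without copia, 61.0% to 75.6% of the transposon counts per library lay in the last 10% of the consensus sequences. Copia reads ended most often at position 5076 of 5143 in all 4 libraries, with 10688 reads there in siGFP and 21036 in siPIWI OSCs. The main position was matched to the exact nucleotide for transposons with at least 50 reads in each library of a pair. It was the same in both OSC libraries for 20 of 27, in both ovary libraries for 3 of 7 and in both knockdown libraries for 5 of 12. Between the knockdown libraries, the differing positions lay close for Doc (4713 and 4701), Stalker2 (7600 and 7613) and DNAREP1 (587 and 563). They lay farther apart for '1360', blood, mdg1 and pogo. ZAM reads ended most often at position 8309 of 8435 (317 reads in knockdown ovaries, 41 in siPIWI OSCs), gypsy reads at 7260 of 7469 (122 and 3109) and springer reads at 7340 of 7546 (118 and 9062).

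In '412' and mdg1 a second set of ends lay far upstream, and its share differed between control and knockdown for '412' in both comparisons and for mdg1 in OSCs. Such ends were not particular to these elements. In siPIWI OSCs 1167 of 3759 blood reads ended within 25 nt of position 1672, 373 of 2148 Stalker2 reads near 1338 and 217 of 668 Tabor reads near 1209. Outside the mdg1 group, 897 of 1432 invader4 reads ended near 1372 and 316 of 1647 mdg3 reads near 1701. In control ovaries only 5.86% of '412' reads (3.32 to 9.48) ended in the last 30% of the element, and 63 of 256 ended at position 1452 of 7567. In vreteno knockdown ovaries 44.6% (41.4 to 47.9) did so, and the main position was 7522, with 253 reads. In OSCs this held for 2 of 20 reads of '412' with siGFP (95% interval 1.24% to 31.7%) and for 53.7% (52.2 to 55.1) with siPIWI. For mdg1 the share was 6.74% (2.51 to 14.1) and 55.8% (54.7 to 56.9), and the main position moved from 1281 to 7412 of 7480. In ovary this held for 3 of 10 mdg1 reads (6.67% to 65.3%) in the control and 53 of 131 in the knockdown (40.5%, upper bound 49.4%), with no difference detectable at this depth, and its main position with the knockdown was 1281. In OSCs, reads ending upstream were also more numerous in the knockdown, by 62.7-fold (39.6 to 106) for '412' and 21.8-fold (upper bound 27.5, lower bound above 1) for mdg1. For '412' in ovary the fold was 2.32 (1.98 to 2.71), and 0.966 (0.827 to 1.13) when scaled to total transposon reads.

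Of the 54 transposons with at least 10 reads in both OSC libraries, 13 had a larger share of ends in the last 30% with siPIWI, with separate intervals, and 1 had a smaller share (mdg3, from 51.3% to 42.7%). Of the abundant mdg1-group elements, blood was at 47.4% (41.7 to 53.1) and 48.6% (47.0 to 50.2). Gypsy went from 62.3% (57.2 to 67.2) to 92.9% (92.4 to 93.4), Stalker2 from 30.5% (22.8 to 39.2) to 53.1% (50.9 to 55.2) and springer from 83.3% (82.5 to 84.1) to 89.6% (89.3 to 89.9). Most upstream gypsy ends lay in the 5' terminal repeat described below, 123 of 142 with siGFP and 677 of 807 with siPIWI. Its shift cannot be told apart from the placement of reads between the repeats. In ovary '412' was the only one of 30 with separate intervals.

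**Figure D3:**
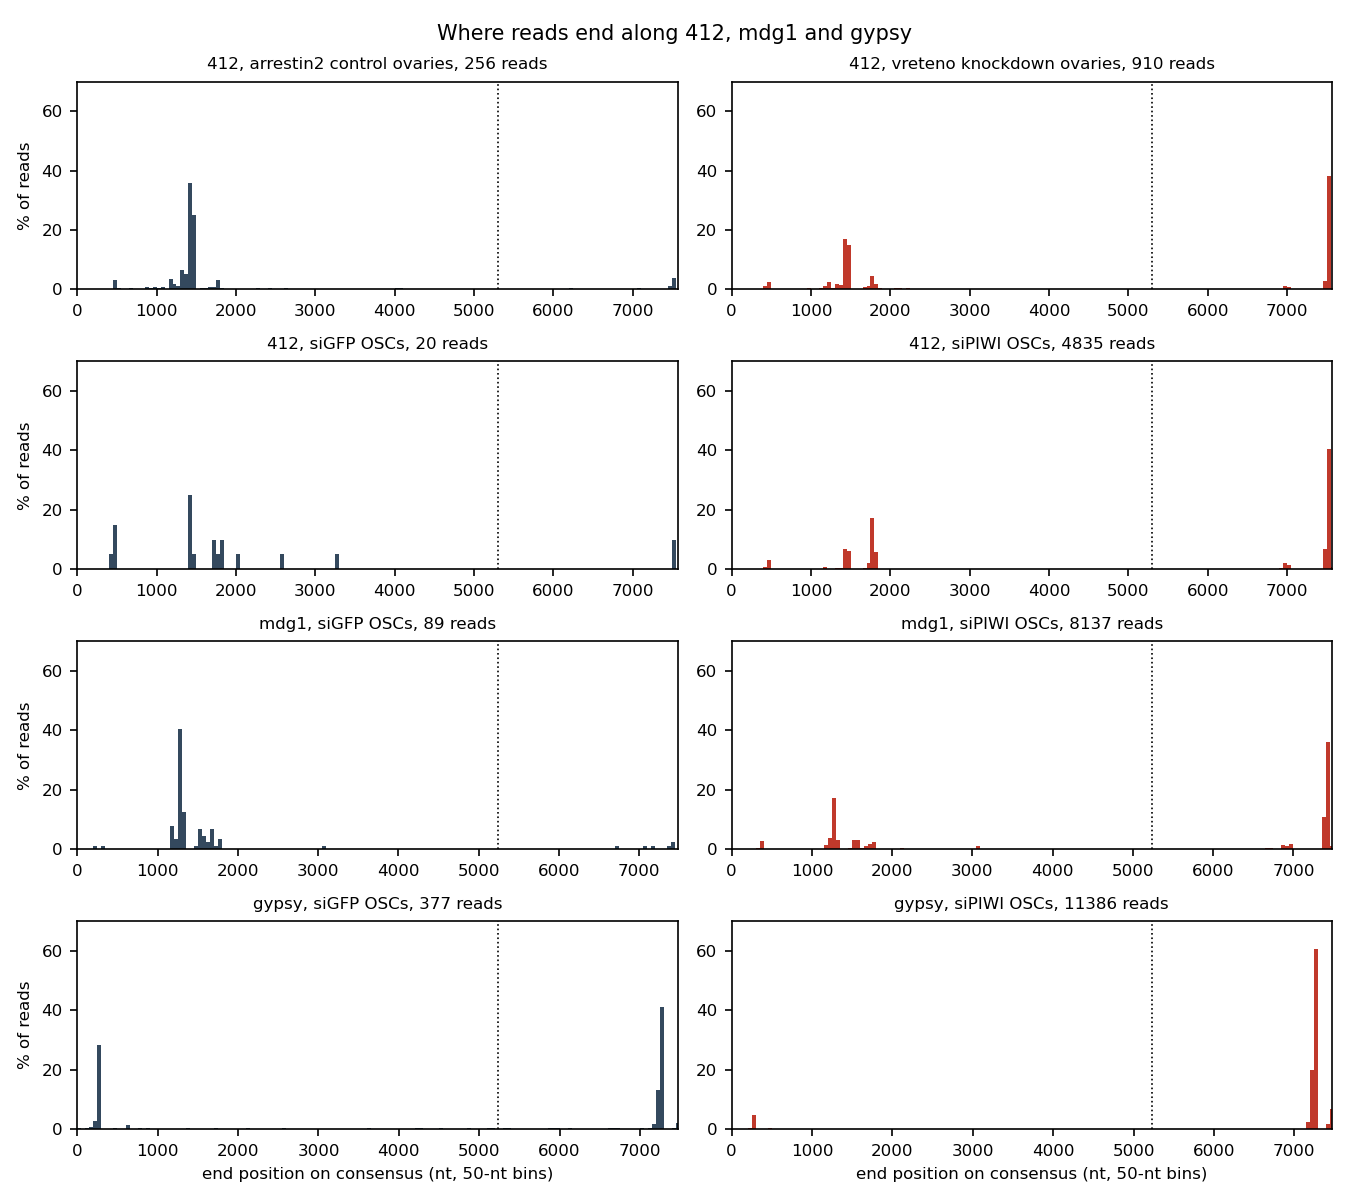
Percent of an element's reads (y axis) that ended in each 50-nt bin of its consensus (x axis, nt), with control libraries on the left, knockdown libraries on the right and the dotted line at 70% of the length. The element '412' is plotted for both comparisons, and mdg1 and gypsy for OSCs alone. Ends of '412' in the control ovaries and of mdg1 in siGFP OSCs cluster near 1452 and 1281 (6 of 20 ends of '412' with siGFP lie near 1452), and near 7522 and 7412 as well in the knockdowns, and gypsy ends near 273 and 7260.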

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

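All tests of explanations in this part except that of library scaling for ZAM were chosen after the result was seen. The fold in OSCs was set against the fold in ovary for the 39 transposons past the minimum in both comparisons with reads in all 4 libraries. The intervals on the log2 difference (OSC minus ovary, normal approximation to the counting error) were widened for 39 comparisons and compare libraries, not conditions. They excluded 0 for 10 elements with scaling by the median ratio, and for 4 of these, ZAM, springer, '297' and '412', under each of 4 scalings. The fold was larger in ovary for ZAM (log2 difference -5.87), springer (-4.06), gypsy (-2.42) and copia (-0.94), though for copia the difference was -0.21 with total scaling and 0.20 unscaled, and for gypsy the interval included 0 with both. It was larger in OSCs for Doc (1.43), mdg1 (1.67), '17.6' (2.01), flea (2.24), '297' (3.29) and '412' (4.95), and the intervals of Doc, mdg1, '17.6' and flea included 0 with non-transposon scaling. A fold also depends on the control level. Control ovaries and siGFP OSCs had 2382 and 57045 transposon reads. Of these, 256 and 20 were '412', 15 and 9220 springer, 3 and 17 ZAM and 13 and 87 '297'. In the knockdowns '412' had 910 of 5156 reads in ovary and 4835 of 164243 in OSCs. How far control levels account for the differences was not tested. Among the sequences outside the transposon comparisons, the rDNA spacer was at a fold of 1.19 (1.04 to 1.36) in siPIWI OSCs, from 311 to 735 reads. This is within the interval of the median scaling, 0.754 to 1.28. The fold was 0.821 (0.718 to 0.940) when scaled to total transposon reads and 1.46 (1.27 to 1.67) when scaled to the other non-transposon reads.

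ZAM was 211.5-fold higher in the ovary knockdown and 3.62-fold in the OSC knockdown. The scaling of the libraries cannot account for this alone: over all pairs of 4 scalings the smallest difference of log2 ratios was 3.40, beyond the counting error. Reads of a related element placed on ZAM in ovary stay open, since 63.4% of the ovary reads (59.3 to 67.3) and 36.1% (27.6 to 45.3) of the siPIWI OSC reads ended within 25 nt of position 8309, so use of this site differed and a close relative may share it. A biological difference also stays open: ovary and OSCs differ in tissue, in genotype and in the gene knocked down, and the log2 difference of -5.87 cannot be told apart between these with 1 library each.

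In OSCs the ends of 13 elements, among them '412', mdg1 and gypsy, lay more often in the last 30% of the element with siPIWI; in ovary this held for '412' alone. An unchanged pool of upstream-ending RNA beside the RNA that increased is argued against as the whole cause in OSCs for '412' and mdg1. Their upstream ends were 62.7-fold and 21.8-fold higher, and above 1 under each of 4 scalings. Gypsy's were 2.86-fold higher, also above 1 under each scaling. But 86.6% of them with siGFP and 83.9% with siPIWI lay in the 5' terminal repeat described under other observations. Reads of the 3' repeat placed there would rise with the element, so gypsy does not test such a pool. Upstream ends were above 1 under each of 4 scalings for 7 of the 13 elements. These include '297' and Quasimodo, where 71.85% and 87.0% of the upstream ends with siPIWI also lay in the 5' repeat, so the same limit holds. For 5 of the 13 the interval with scaling by the median ratio included 1, as for springer at 1.06 (0.994 to 1.12), so such a pool may account for their shift. It also stays open for '412' in ovary, where the fold of 2.32 became 0.966 (0.827 to 1.13) with total scaling. Capture of RNA at internal sites, the placement of reads by the aligner and different silencing of copies with different 3' ends were not tested.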

How the results depend on the processing

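Scaling to non-transposon reads, the alternatives for the share of read ends and the floor in place of the pseudocount, and all scalings of upstream ends, of non-transposon sequences and of the differences between comparisons were chosen after the data were seen. No paired analysis was possible because each group had 1 library, and no library could be left out, so the alternatives change the processing of the same reads. Over the alternatives, Pearson's r between the 2 comparisons was 0.491 to 0.609 and Spearman's rho 0.495 (without a minimum) to 0.736. Of 127 alternative list medians, 80 stayed within the counting interval of the main value, 45 moved outside it and 2 changed sign where the main interval excluded 0; of 312 for single elements 216, 91 and 5 did. Counting also values whose main interval included 0, the sign changed for 26 medians and 22 element values, 14 and 16 of them by scaling. Before the pseudocount, total transposon reads shift all log2 ratios by -1.26 in ovary and -0.54 in OSCs. No scaling shifts them by -0.15 and 0.99, and non-transposon reads by 0.58 and -0.11. With the pseudocount, elements with few reads shift by less. Without copia, the total rose 5.06-fold rather than 2.88-fold between the OSC libraries, so a total follows the elements that changed. The causes of the other shifts were not tested. The elements past the minimum were 45 of 124 in ovary and 73 in OSCs, which differ in depth and in tissue.

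The ovary count of 11 elements at least 4-fold higher became 7 with a pseudocount of 10 reads, 6 of 16 tested with a minimum of 50 reads, 7 with total scaling and 19 at a 2-fold threshold. It was 8 with the highest single position, 13 without a minimum and with ends in the last 30%, and 16 with non-transposon scaling. The ovary count of lower elements, 0, became 1 without a minimum and 2 with total scaling. The OSC counts of 18 and 0 became 28 and 4 at 2-fold. The 18 became 12 with a pseudocount of 10 reads, 14 with total scaling and with a minimum of 50 reads, 17 with non-transposon scaling and with the floor for elements at 0 control reads, 25 with ends in the last 30% and 26 unscaled. The overlap of 8 became 4 with a pseudocount of 10 reads, with a minimum of 50 reads and with total scaling, against 1.58, 2.14 and 1.75 for independent lists. It was 6 with the highest single position, 9 without a minimum and with non-transposon scaling, 10 unscaled and 11 with ends in the last 30%. The 13 OSC elements with more ends in the 3' part became 8 with at least 50 reads in both libraries. In ovary, total scaling gave medians of 0.98 for the gypsy group, 1.85 for the mdg1 group, -0.72 for other Ty3/gypsy, -1.41 for Bel-Pao, -0.87 for copia-like, -1.68 for telomeric, -1.16 for non-LTR and -1.41 for DNA elements. A pseudocount of 10 reads gave 1.04 for the gypsy group and 2.27 for the mdg1 group. A minimum of 50 reads gave 6.07 for the gypsy group (3 members), -0.24 for other Ty3/gypsy and 1.0 for copia-like (1 member each). The highest single position gave 2.0 for the mdg1 group, -0.26 for other Ty3/gypsy and -0.49 for DNA elements. Non-transposon scaling gave 1.06 for other Ty3/gypsy, 0.37 for Bel-Pao, 0.63 for non-LTR and 0.39 for DNA elements.

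In OSCs, total scaling gave 1.42 for the gypsy group, 3.75 for the mdg1 group, -0.50 for other Ty3/gypsy, -1.01 for Bel-Pao, -0.47 for copia-like, -0.58 for telomeric and -0.82 for DNA elements. Unscaled reads gave 2.93, 5.26, 1.03, 0.51, 1.06, 0.89 and 0.70 in the same order, and 1.70 for non-LTR. Ends in the last 30% gave 5.20 for the mdg1 group, 0.22 for other Ty3/gypsy, -0.19 for Bel-Pao, 0.32 for copia-like and 1.28 for non-LTR. A pseudocount of 10 reads gave 1.66 for the gypsy group and 3.90 for the mdg1 group. The copia-like list was at -0.15 with a minimum of 50 reads and at -0.04 with non-transposon scaling. The non-LTR list was at 0.12 without a minimum, at 1.33 with 50 reads and at -0.09 with the highest single position. Of the single elements whose main interval excluded a fold of 1, the sign changed for copia with total scaling (-0.26 in ovary, -0.47 in OSCs) and non-transposon scaling (-0.04 in OSCs), pogo in ovary with non-transposon scaling (0.08) and the I-element in ovary with the highest single position (-0.09). Among those whose interval included it, '297' (-0.28) and Doc (-1.16) in ovary did so with total scaling, DNAREP1 (0.48) with non-transposon scaling and '17.6' (1.05) with ends in the last 30%. In OSCs HeT-A (0.56), roo (0.68) and mdg3 (0.95) did so unscaled, gypsy12 (-0.49) and invader4 (-0.50) with total scaling and roo (0.12) with ends in the last 30%. The fold of '412' upstream ends in ovary became 0.966 and that of the rDNA spacer in OSCs 0.821 with total scaling. That of the region labelled kipf in ovary became 1.15 with scaling to the other non-transposon reads. The log2 difference of copia between comparisons became 0.20 unscaled. Coverage drops and antisense shares were planned and not run, because the files hold read ends without strand.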

Other observations

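Which elements are named in the first 2 paragraphs was chosen after their values were seen, as was the test in the last one. The sequences that are not transposons gave 406 and 245 reads in the ovary libraries and 446 and 954 in the OSC libraries. A region labelled kipf, a label not matched to a gene here, had 221 reads in control and 142 in knockdown ovaries (0.711-fold, 0.572 to 0.882). In OSCs this region had 43 and 61 reads (0.715-fold, 0.476 to 1.08). Scaled to the other non-transposon reads, which are mostly the rDNA spacer, it was at 1.15-fold (0.928 to 1.43) in ovary and 0.640-fold (0.426 to 0.969) in OSCs. Stellate, a multicopy gene family, had 34 and 23 reads in ovary and 66 and 96 in OSCs (0.749-fold, 0.421 to 1.31, and 0.733-fold, 0.530 to 1.02). The rDNA spacer had 139 and 70 reads in ovary (0.558-fold, 0.412 to 0.748). It was at 0.768-fold (0.568 to 1.03) when scaled to the other non-transposon reads, which are mostly the kipf region. All 3 Responder satellite sequences had 0 reads in all 4 libraries.

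The control libraries of ovary and OSCs differed in single Ty3/gypsy elements. As copia took most OSC reads, shares of the transposon reads without copia are given (1884 reads in control ovaries, 15268 in siGFP OSCs). For invader4 the share was 4.6% (4.28 to 4.95, 703 reads) in siGFP OSCs. It had 0 reads in control ovaries, which allows up to 0.159% on the floor of 3 reads and 0.196% by the exact upper bound. Burdock had 3.77% (2.96 to 4.73, 71 reads) in control ovaries and 0.0131% (0.00159 to 0.0473, 2 reads) in siGFP OSCs. These intervals compare 2 libraries, which differ in tissue and genotype.

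Read ends near the 5' end of several LTR elements appeared to mirror those near the 3' end, as the pair at positions 273 and 7260 of gypsy. The hypothesis that both terminal repeats share 1 set of end sites was tested by correlating the read ends over the first and the last part of each element, for every length of that part from 100 nt to 15% of the element, in siPIWI OSCs. Of 11 elements with at least 50 reads in both outer 15% parts, 8 had a single clear offset (profile correlation of at least 0.7, any other below 0.5). The offset implied a terminal repeat of 482 nt in gypsy (r = 0.89), 442 nt in mdg1 (0.88), 514 nt in '412' (0.88), 659 nt in Quasimodo (0.84), 409 nt in springer (0.81), 414 nt in '297' (0.81), 274 nt in copia (0.75) and 424 nt in Stalker2 (0.72). The elements '1360', TART-A and gypsy12 showed none. In siGFP OSCs copia alone of 4 elements met this rule; gypsy and springer gave the same lengths as in siPIWI OSCs, 482 and 409 nt, with a next best correlation of 0.54 and 0.51. In gypsy the 5' repeat held 83.9% (81.2 to 86.4) of the upstream ends, and in mdg1 and '412' only 7.31% (6.48 to 8.21) and 8.39% (7.27 to 9.61). Ends in the 5' repeat may come from RNAs that stop there, from solo repeats or from reads placed on the wrong copy, and the 8 elements do not separate these. The upstream ends of mdg1 and '412' near 1281 and 1452 lie outside the implied repeat.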
